A study of Mus musculus with 6 samples.

How the data were processed

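Poly(A) RNA from 6 cultures of differentiated white adipocytes (3 control, 3 DICER_KO) was made into NEBNext Ultra II libraries and sequenced as read pairs on an Illumina NovaSeq, per the labels and the series' design text. The values deposited by the authors are log2 CPM, with 1 column for each library and 0 columns of other samples. The submitters' processing notes name FastQC, Trimmomatic, HISAT2, featureCounts and edgeR, and the builds mm10 and GRCm38, without versions, roles or order. The kit and counting are not stated to use strand, so reads of overlapping antisense genes cannot be told apart.

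The deposited log2 values were checked against a formula. Every value equals the log2 of (k + 0.5) / (N + 1), scaled to CPM, for a whole number of reads k, with 100% of values whole at a tolerance of 0.01 reads and a largest deviation of 3.37e-08. N is the library size that the values imply, and ran from 17594568 to 42331787. The series' design text names TMM scaling in edgeR, so N may be a scaled size and not a count of reads. Reads on the 13734 genes in the table came to 71.5 to 77.1% of N, and reads on any other genes are not analysed here. Gene IDs are Entrez numbers: 13682 matched a symbol in the RefSeq annotation of GRCm38.p6 and 52 did not, and coordinates come from that annotation. List entries were matched by symbol, 3 of them by an older symbol, and 569 of 699 entries in 29 lists had a value. Of these lists 28 had tested genes, and the list of mitochondrially encoded genes is not analysed here. The genes Lep and Csf1, which the rule for named genes also holds, are not analysed here.

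The test had been fixed before the data were examined, as were the groups, gene lists, named-gene rule and most alternatives. The plan was a count model, or limma with an intensity trend on log2(CPM + 1) if the file held CPM. That form on log2(CPM + 1) was run as an alternative and called 13 genes higher and 28 lower in DICER_KO. The deposited unit is log2 CPM, and limma 3.58.1 with an intensity trend (R 4.3.3) was fitted to the deposited log2 values with the group as the only term. Whole reads could be recovered from these values, but the planned count models were not run on them. Of tests that use the recovered reads, limma-voom was run as an alternative. Genes with at least 1 CPM in at least 3 libraries entered (10054 genes). Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and fold changes are DICER_KO minus control on the log2 CPM scale, which understates changes of low genes. Gene lists were tested with camera at a preset correlation of 0.01 and with a correlation estimated per list, adjusted over 28 lists. The direction of each list was also taken from fry. At a preset correlation 12 lists passed, and 0 held with an estimated correlation. The lists share 32 genes that belong to more than 1 list. The count adjusted over the list alone applies the same correction within each list.

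The named genes are Dicer1, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM, separated groups and an assigned symbol, up to 2 risers and 2 fallers past the threshold in each list (or the member with the smallest p), and a fixed set of genes of adipocyte function and inflammation. A result on 1 gene that this rule names is not reported here. For seed matches, the longest annotated 3' UTR of each gene was taken from GENCODE M21 (GRCm38), which gave 9509 tested genes with a median length of 1370 bases. Of the 9575 tested protein-coding genes 99.2% had such a 3' UTR. Median fold changes of genes with and without a match were compared within 10 bins of 3' UTR length and averaged over the bins, weighted by the genes with a match. The difference was set against up to 200 shuffled seeds of the same bases, each matched in at least 20 genes. The smallest p that 200 shuffled seeds can give is 0.005, and families with few distinct orders had fewer shuffled seeds (104 for let-7).

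On data simulated with 200 changed genes the test found 93% of 100 changes of 1 on the log2 scale and 100% of 100 changes of 2, with 10 false calls among 10054 genes. Without DICER_KO replicate 3 it found 91% of changes of 1, while calls in the real data rose from 44 to 1983. The simulation did not carry the effect of that library, so 93% is not the share of real changes found. Libraries of 1 group were compared by a chi-square of reads over genes with at least 20 reads in both. It was 8.36 per degree of freedom between DICER_KO replicates 1 and 2, 85.5 and 92.8 between these and replicate 3, and 12.1 to 26.4 between controls, so no pair was the same library. Alternatives changed the scaling, the filter, the pseudocount, the test, the replicate term and the libraries, leaving out each in turn. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.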

Results

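Messenger RNA was sequenced from white adipocytes differentiated from an immortalized mouse subcutaneous preadipocyte line that carries floxed Dicer1 alleles and a tamoxifen-activated Cre recombinase. Dicer1 encodes the RNase that cuts microRNA precursors into mature microRNAs. On day 6 of differentiation the cells received 10 µM 4-hydroxytamoxifen for 48 h to delete Dicer1 (DICER_KO, 3 libraries) or ethanol (control, 3 libraries). All 6 cultures then received the beta-adrenergic agonist isoproterenol at 10 µM for 6 h, so every comparison is between stimulated cells. The labels call the libraries biological replicates of the line without saying whether cultures were differentiated separately, and p-values measure the spread between these libraries. The analysed genes held 17680469, 17219155 and 17317210 reads in controls 1 to 3, and 13569034, 18443315 and 30268077 reads in DICER_KO replicates 1 to 3. The comparison asks how loss of Dicer1 changes the transcripts of lipid metabolism and of signals between adipocytes and macrophages. Because each DICER_KO library was exposed to 4-hydroxytamoxifen and no control was, a difference between the groups belongs to the deletion and the drug together.

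Dicer1 was lower in every DICER_KO library than in every control. Its level was 6.12 ± 0.03 log2 CPM (reads scaled to library size) in controls (SD, n = 3) and 5.46 ± 0.03 in DICER_KO (SD, n = 3). The libraries read 6.14, 6.09 and 6.14 in controls, and 5.43, 5.47 and 5.49 in DICER_KO. Dicer1 (Entrez 192119; GRCm38 chromosome 12, 104687740 to 104751968) fell by 0.66 on the log2 scale (SE 0.10, limma adjusted p = 0.0150), to 0.633 of the control level. A gene-level value also counts reads from exons that a floxed allele keeps, so it is not the share of undeleted alleles. The adjusted p missed the threshold without control replicate 1 (0.147), 2 (0.0722) or 3 (0.0841) and without DICER_KO replicate 1 (0.0568) or 2 (0.0653), while the log2 difference stayed between -0.68 and -0.64.

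Of 10054 genes tested, 15 rose and 29 fell in DICER_KO. The largest rises were in Cyp2f2, a cytochrome P450, by 3.97 on the log2 scale (SE 0.53, adjusted p = 0.00983), and in Itih4, a secreted acute-phase protein, by 3.10 (SE 0.31, adjusted p = 0.00384). Cyp2f2 read 5.44, 5.32 and 3.02 log2 CPM in DICER_KO replicates 1 to 3, and without replicate 3 it rose by 4.76 (adjusted p = 1.56e-09). Itih4 (Entrez 16427; chromosome 14, 30886476 to 30901986) stood at 2.87 ± 0.12 log2 CPM in controls and 5.97 ± 0.82 in DICER_KO (SD, n = 3). Slco2b1, an organic anion transporter, rose by 1.85, and Acod1, the enzyme that makes itaconate, rose by 1.59. Cyb561, a transmembrane cytochrome, rose by 1.16, the secreted protease inhibitor Slpi by 1.13, the Rab GTPase-activating protein Tbc1d16 by 1.00 and the secreted glycoprotein Creg1 by 0.95. The monoacylglycerol lipase Abhd6 rose by 0.93 and the stearoyl-CoA desaturase Scd3 by 0.88. Scd3 has close relatives in the same gene cluster, so reads may have been split between them.

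Among the genes that fell, Prg4, which encodes lubricin, had the smallest p of all genes. Prg4 (Entrez 96875; chromosome 1, 150449412 to 150466221) stood at 8.61 ± 0.17 log2 CPM in controls and 6.97 ± 0.06 in DICER_KO (SD, n = 3), a difference of -1.65 (SE 0.11, adjusted p = 0.000223). The matrix protein gene Spon1 fell by 2.12, Abi3bp fell by 1.29 and the short-chain collagen gene Col8a1 fell by 1.18. Col3a1 (Entrez 12825; chromosome 1, 45311538 to 45349706), the fibrillar collagen III gene, stood at 11.02 ± 0.06 in controls and 9.58 ± 0.36 in DICER_KO (SD, n = 3), a difference of -1.44 (SE 0.17, adjusted p = 0.00856). Nr4a1, an orphan nuclear receptor induced by cyclic AMP, fell by 1.16, and the vasopressin receptor gene Avpr1a fell by 1.14. The neutrophil chemokine gene Cxcl5 fell by 1.09, the retinol dehydrogenase gene Rdh10 fell by 0.98 and Fam110c fell by 1.71.

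**Figure D1:**
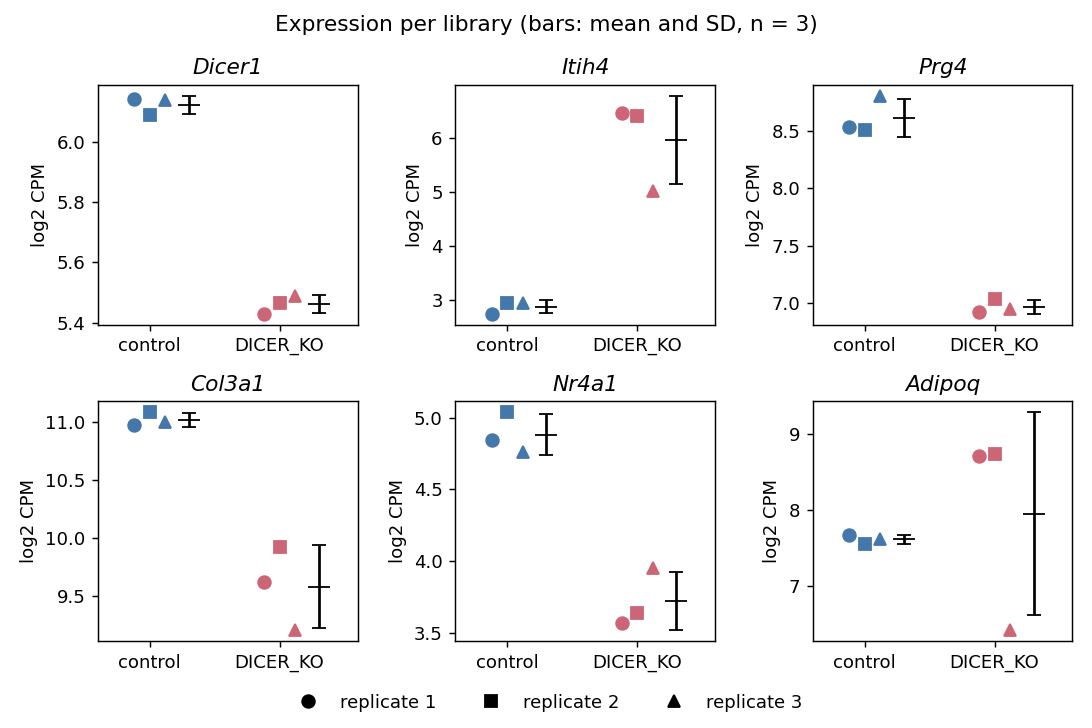
Each panel plots the log2 CPM of 1 gene in the 6 libraries, with symbols for replicates 1 to 3 and a black bar for the mean and SD of each group (n = 3). Dicer1, Prg4, Col3a1 and Nr4a1 lie lower and Itih4 lies higher in every DICER_KO library than in every control, while Adipoq lies at 8.71 and 8.74 in DICER_KO replicates 1 and 2 and at 6.41 in replicate 3, below the controls.

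In all 44 of these genes every DICER_KO library lay on the same side of every control, which a test on the same libraries selects for. Over all genes tested 20.2% were separated in this way, where chance gives 10%. The number of calls at the adjusted threshold changed when single libraries were left out. Without DICER_KO replicate 3 it was 1257 higher and 726 lower, and all 44 genes were among them. Leaving out each library was planned, but this fit is shown throughout because replicate 3 lay apart. Its p-values leave out the spread that replicate 3 adds, so they are smaller than the DICER_KO libraries together warrant. Without control replicate 1, 2 or 3, 11, 10 and 1 of the 44 genes remained past the threshold, and without DICER_KO replicate 1 or 2, 27 and 17 of them did. Genes with an unadjusted limma p under 0.05 numbered 870, 847 and 1911 without control replicates 1, 2 and 3. With all libraries they numbered 1593, so the single call without control replicate 3 does not mean fewer differences there.

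The known miR-29 matrix targets, collagens and other extracellular matrix genes, ranked lower in DICER_KO as a set. Col3a1 fell and Col5a2 fell by 0.87 (SE 0.11, adjusted p = 0.00959), and 11 of 13 tested members did not pass over all genes; adjusted over the list alone, 7 fell and 0 rose. The counts without DICER_KO replicate 3 were 8 that fell and 0 that rose by either adjustment, over all genes or adjusted over the list alone. The median difference with all libraries was -0.37 (camera adjusted p = 5e-07; adjusted p = 0.424 with an estimated correlation). In DICER_KO replicates 1, 2 and 3 the list's median lay at -0.33, -0.31 and -0.56 against the control mean. Of 21 tested preadipocyte and fibroblast markers, Col3a1 alone passed over all genes, and 5 fell and 0 rose adjusted over the list alone. Leaving out DICER_KO replicate 3, 7 fell and 1 rose over all genes, and 9 and 1 adjusted over the list alone. With all libraries their median was -0.30 (camera adjusted p = 1.19e-05; adjusted p = 0.326 with an estimated correlation).

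Genes of the beta-adrenergic and cyclic AMP response ranked lower as a set. Nr4a1 fell and the other 20 of 21 tested members did not pass over all genes; adjusted over the list alone, 9 fell and 1 rose. In the fit without DICER_KO replicate 3, 8 fell and 4 rose over all genes, and 10 and 4 adjusted over the list alone. With all libraries the median was -0.29 (camera adjusted p = 7.05e-06; adjusted p = 0.162 with an estimated correlation). In the integrated stress and unfolded protein response list, Atf3, a stress-induced transcription factor gene, fell by 0.87 (SE 0.12, adjusted p = 0.0139), and 4 of 23 members fell and 0 rose adjusted over the list alone. There, 8 fell and 2 rose over all genes without DICER_KO replicate 3, and 10 and 2 adjusted over the list alone. With all libraries that list's median was -0.20 (camera adjusted p = 5.59e-05; adjusted p = 0.326 with an estimated correlation). None of the 20 tested senescence and secretory genes passed over all genes and 3 fell adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.00132; adjusted p = 0.25 with an estimated correlation). Leaving out DICER_KO replicate 3 gave 9 senescence and secretory genes that fell and 3 that rose over all genes, and 11 and 4 adjusted over the list alone. With all libraries Il6, which encodes an inflammatory cytokine, differed by -0.86 (adjusted p = 0.0883), and without DICER_KO replicate 3 it fell by 0.77 (adjusted p = 0.00622). Of 18 p53 targets 0 passed over all genes, 1 rose and 1 fell adjusted over the list alone, and the set test gave adjusted p = 0.665. Of these p53 targets, 1 rose and 4 fell over all genes without DICER_KO replicate 3, and 2 and 4 adjusted over the list alone. With all libraries the member with the smallest p, Gdf15, differed by -0.58 (adjusted p = 0.133), and the cell cycle inhibitor gene Cdkn1a by -0.22 (adjusted p = 0.364). Gdf15 fell by 0.74 without DICER_KO replicate 3 (adjusted p = 0.000487).

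Genes of the mature adipocyte differed in direction between the DICER_KO libraries, with replicate 3 opposite to the other two. Adipoq, which encodes adiponectin, stood at 7.61 ± 0.06 log2 CPM in controls, and at 8.71, 8.74 and 6.41 in DICER_KO replicates 1, 2 and 3. None of 20 tested members of the list passed over all genes, and adjusted over the list alone 0 rose and 1 fell. The list's median was 0.26, its mean lay slightly below 0 and its set test pointed up (camera adjusted p = 0.905). Its median against the control mean was 0.64, 0.70 and -1.03 in DICER_KO replicates 1, 2 and 3. Without DICER_KO replicate 3, 16 members rose and 1 fell over all genes, 17 and 2 adjusted over the list alone, with a median of 0.66 (camera adjusted p = 8.35e-10; adjusted p = 0.141 with an estimated correlation). Without DICER_KO replicate 2 the list's median was -0.06 (camera adjusted p = 0.0488 at the preset correlation). With all libraries and an estimated correlation camera gave adjusted p = 0.970. Car3, a carbonic anhydrase gene of adipocytes, had the smallest p of the list and differed by -2.43 (adjusted p = 0.116). Without DICER_KO replicate 3, Car3 fell by 1.48 (adjusted p = 4.17e-05), opposite to the list's median, and without replicate 2 Car3 fell by 3.09 (adjusted p = 0.0338).

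No member of the mature adipocyte list passed with all libraries, and several did without DICER_KO replicate 3. P-values without replicate 3 leave out the library that disagreed, so they do not show a rise across all DICER_KO libraries. With all libraries, the differences were 0.34 for Adipoq (adjusted p = 0.732), 0.26 for the fatty acid carrier gene Fabp4 (0.763), 0.36 for Pparg (0.319), -0.77 for the fatty acid transporter gene Cd36 (0.363), 0.08 for the triglyceride lipase gene Pnpla2 (0.911) and -0.02 for the hormone-sensitive lipase gene Lipe (0.979). Without DICER_KO replicate 3, Adipoq rose by 1.11 (adjusted p = 1.49e-06), Fabp4 by 0.90 (0.000472), Pparg by 0.58 (0.000629), Pnpla2 by 0.61 (0.00119) and Lipe by 0.62 (0.000557), while Cd36 differed by -0.15 (0.339). Cd36 lay below the control mean of 8.79 log2 CPM in each DICER_KO library, at 8.55, 8.73 and 6.78.

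Genes of mitochondrial fuel use ranked higher as sets, with values in DICER_KO replicate 3 below the controls. None of the 22 tested fatty acid oxidation genes passed over all genes or adjusted over the list alone, and their median was 0.33 (camera adjusted p = 0.000466; adjusted p = 0.731 with an estimated correlation). The 42 nuclear-encoded oxidative phosphorylation genes all had positive differences, 0 passed over all genes or adjusted over the list alone, and their median was 0.28 (camera adjusted p = 2.35e-07; adjusted p = 0.731 with an estimated correlation). For 17 genes of branched-chain amino acid breakdown, 0 passed by either adjustment, over all genes or adjusted over the list alone, and the median was 0.34 (camera adjusted p = 0.00191; adjusted p = 0.731 with an estimated correlation). In DICER_KO replicate 3 the medians of these lists lay at -0.26, -0.15 and -0.26 against the control mean. Without that library 21 of 22 fatty acid oxidation genes, 42 of 42 oxidative phosphorylation genes and 15 of 17 genes of branched-chain amino acid breakdown rose over all genes, and 21, 42 and 16 adjusted over the list alone (camera adjusted p = 4.61e-16, 6.62e-20 and 2.88e-10; adjusted p = 0.141 with an estimated correlation for each). Without DICER_KO replicate 1 the set tests of fatty acid oxidation (adjusted p = 0.0591) and of branched-chain amino acid breakdown (adjusted p = 0.0693) missed the threshold. The members with the smallest p were Ehhadh (0.70, adjusted p = 0.241), Uqcrb (0.46, 0.225) and Bcat2 (0.63, 0.289). In the fit without DICER_KO replicate 3 they rose by 1.04 (adjusted p = 6.14e-05), 0.62 (0.00154) and 1.02 (5.69e-06).

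The lists of lipid synthesis, lipid droplet and thermogenic genes passed no set test with all libraries. In fatty acid and triglyceride synthesis (19 tested), lipolysis and lipid droplet (17) and thermogenic genes (16), 0 members passed over all genes, and 0, 1 and 1 rose adjusted over the list alone. The medians were 0.14, 0.08 and 0.27 (camera adjusted p = 0.212, 0.651 and 0.141). Against the control mean they lay at -0.40, -0.76 and -0.23 in DICER_KO replicate 3. Without that library 12, 14 and 8 members rose and 1, 1 and 0 fell over all genes, and 15, 15 and 11 rose and 1, 1 and 0 fell adjusted over the list alone (camera adjusted p = 1.91e-07, 1.68e-07 and 0.000105; adjusted p = 0.141 with an estimated correlation for each). With all libraries the triglyceride-synthesis gene Dgat2 differed by 0.70 (adjusted p = 0.226), Plin3, a lipid droplet coat gene, by 0.56 (0.0574), the potassium channel gene Kcnk3 by 1.18 (0.0965) and Scd1 by 0.47 (0.506). Fasn differed by -0.28 (0.248) and Acaca by 0.00 (0.998). Ucp1, the uncoupling protein gene, differed by -0.23 (0.814), with DICER_KO values of 3.02, 2.65 and 0.76 log2 CPM against 2.37 ± 0.03 in controls (SD, n = 3), and Ppargc1a, its coactivator gene, by 0.63 (0.442). Without DICER_KO replicate 3, Scd1 rose by 1.02 (4.4e-05), Dgat2 by 1.03 (1.92e-05), Kcnk3 by 1.58 (2.1e-07) and Ppargc1a by 1.26 (1.7e-05), and Ucp1 differed by 0.47 (0.0698). In the same fit Plin3 rose by 0.62 (0.000472), Fasn fell by 0.32 (0.0291) and Acaca differed by 0.20 (0.153).

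Cholesterol synthesis and uptake genes ranked lower as a set. Of 22 tested members, 7 fell and 0 rose adjusted over the list alone. The median was -0.24 (camera adjusted p = 7.05e-06; adjusted p = 0.25 with an estimated correlation). Hmgcs1, an early enzyme gene of the pathway, differed by -0.18 (adjusted p = 0.696). The 16 glycolysis and glucose uptake genes had 0 calls over all genes or adjusted over the list alone and a median of -0.13 (camera adjusted p = 0.054). At the preset correlation that set test passed downward without control replicate 1 (adjusted p = 0.0088), control replicate 3 (0.0287) or DICER_KO replicate 2 (0.00374). With all libraries and an estimated correlation camera gave adjusted p = 0.731. In glycolysis 2 rose and 2 fell over all genes without DICER_KO replicate 3, 2 and 3 adjusted over the list alone, and the set test gave adjusted p = 0.503. With all libraries Pfkfb3, a regulator gene of glycolysis, differed by -0.50 (adjusted p = 0.133), and without DICER_KO replicate 3 it fell by 0.40 (adjusted p = 0.0243). The 23 cytosolic ribosomal protein genes had 0 calls by either adjustment, over all genes or adjusted over the list alone, and a median of -0.16 (camera adjusted p = 4.94e-05; adjusted p = 0.731 with an estimated correlation). Leaving out DICER_KO replicate 3, 4 of them fell and 0 rose over all genes, with 0 calls adjusted over the list alone. With all libraries Rps2 differed by -0.26 (adjusted p = 0.268), and without DICER_KO replicate 3 it fell by 0.29 (adjusted p = 0.0426). Reads of ribosomal protein genes can be shared with processed pseudogenes.

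Among macrophage-directed secreted factors and inflammation genes, the chemokine gene Cxcl5 fell and the chemokine gene Cxcl14 fell by 0.77 (SE 0.13, adjusted p = 0.039). The other 25 of 27 tested members did not pass over all genes, and 3 rose and 7 fell adjusted over the list alone. When DICER_KO replicate 3 was left out, 7 rose and 8 fell over all genes, and 8 and 9 adjusted over the list alone. With all libraries members went both ways, with a median of -0.11 (camera adjusted p = 0.121), and Ccl2, a monocyte chemokine gene, differed by 0.30 (adjusted p = 0.268). Without control replicate 2 or DICER_KO replicate 2 the set test passed downward at the preset correlation (adjusted p = 0.0362 and 0.0313). With all libraries and an estimated correlation camera gave adjusted p = 0.731. Of 16 adipokines Rbp4, the retinol binding protein gene, fell by 0.79 (SE 0.11, adjusted p = 0.0139), 4 fell and 0 rose adjusted over the list alone, and the median was -0.09 (camera adjusted p = 0.0688). With an estimated correlation the set test of adipokines gave camera adjusted p = 0.731 with all libraries. At the preset correlation it passed downward without DICER_KO replicate 1 (adjusted p = 0.0162) or 2 (0.00589). Without DICER_KO replicate 3 it pointed up against a median of -0.10 (0.614). Without that library 6 adipokines rose and 5 fell by either adjustment, over all genes or adjusted over the list alone.

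Interferon and double-stranded RNA response genes ranked lower as a set, with the lowest values in DICER_KO replicate 3. Of 40 tested members 0 passed over all genes or adjusted over the list alone, and the median was -0.23 (camera adjusted p = 0.000874; adjusted p = 0.801 with an estimated correlation). The list's median against the control mean was 0.16, -0.17 and -0.66 in DICER_KO replicates 1, 2 and 3. Without replicate 3 the median was -0.02 and the set test pointed up (adjusted p = 0.868), with 7 genes that rose and 2 that fell by either adjustment, over all genes or adjusted over the list alone. With all DICER_KO libraries and without control replicate 1 the set test gave adjusted p = 0.0626. Oas2 had the smallest p and differed by -0.53 (adjusted p = 0.146), and without DICER_KO replicate 3 it fell by 0.35 (adjusted p = 0.0207).

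Lysosomal genes ranked higher as a set. Gpnmb, a glycoprotein gene of lysosomes and macrophages, rose by 0.72 (SE 0.12, adjusted p = 0.034), and 4 of 23 members rose and 0 fell adjusted over the list alone. The median was 0.13 (camera adjusted p = 0.00851; adjusted p = 0.731 with an estimated correlation), and without control replicate 3 the set test missed the threshold (adjusted p = 0.203). When DICER_KO replicate 3 was left out, 8 lysosomal genes rose and 0 fell over all genes, and 9 and 0 adjusted over the list alone. Of 21 genes of the oxidative stress (Nrf2) response 0 passed over all genes and 1 rose adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.0923), and the quinone reductase gene Nqo1 differed by 0.77 (adjusted p = 0.0679). Nqo1 rose by 0.94 without DICER_KO replicate 2 (adjusted p = 0.0219) and by 0.71 without replicate 3 (adjusted p = 0.00262). The set test passed upward without control replicate 1 (adjusted p = 0.0409), DICER_KO replicate 2 (0.00848) or DICER_KO replicate 3 (0.00654; adjusted p = 0.678 with an estimated correlation). In the last of these settings 9 members rose and 1 fell over all genes, and 10 and 1 adjusted over the list alone.

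Of the 17 lipodystrophy genes 0 passed over all genes or adjusted over the list alone, and their median was 0.11 (camera adjusted p = 0.651). Without DICER_KO replicate 3, 9 rose and 1 fell over all genes, 10 and 3 adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.00193; adjusted p = 0.287 with an estimated correlation). Fbn1 had the smallest p and differed by -0.42 with all libraries (adjusted p = 0.131), and without DICER_KO replicate 3 it fell by 0.36 (adjusted p = 0.0202). Of 20 cell proliferation genes 0 passed over all genes or adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.166), and Kif11 differed by 0.35 (adjusted p = 0.228). Of the proliferation genes, 2 fell and 0 rose over all genes without DICER_KO replicate 3, with 0 calls adjusted over the list alone. Of the 3 tested macrophage markers 0 passed over all genes and 1 rose adjusted over the list alone. Their median was -0.16, their mean 0.02 and their set test pointed up (camera adjusted p = 0.827), and Cd68 differed by 0.39 (adjusted p = 0.163). Of the 3 tested endothelial markers 0 passed over all genes and 1 rose adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.934, fry pointing up), and Tek differed by 0.67 (adjusted p = 0.118). When DICER_KO replicate 3 was left out, 1 macrophage marker and 1 endothelial marker rose and 1 endothelial marker fell, over all genes and adjusted over the list alone. Cd68 rose by 0.39 (adjusted p = 0.0334) and Tek by 0.68 (adjusted p = 0.0194) in that fit.

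**Figure D2:**
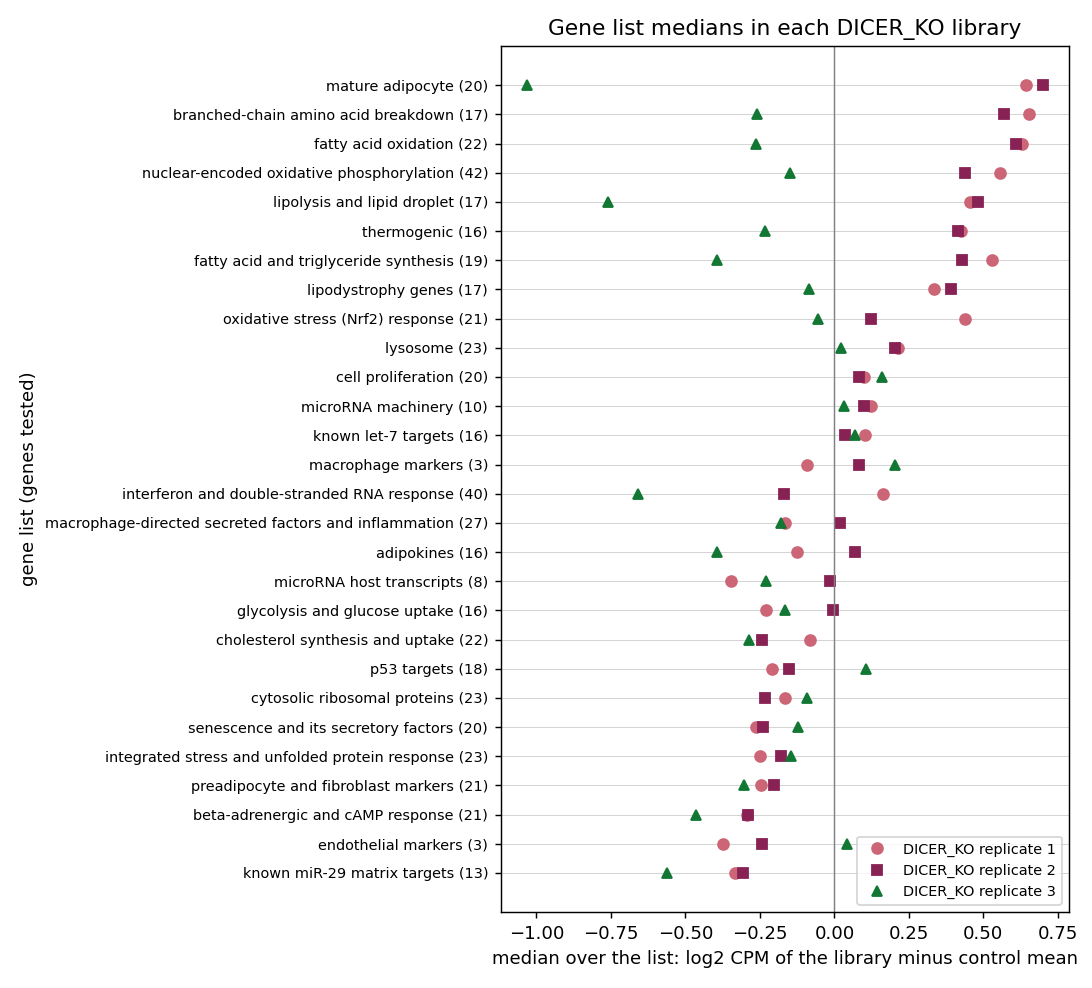
Each point is the median over a gene list of log2 CPM in 1 DICER_KO library minus the control mean, and the number beside each list is its tested genes. DICER_KO replicate 3 lies at -1.03 in the mature adipocyte list where replicates 1 and 2 lie at 0.64 and 0.70, while all 3 libraries lie below 0 in the matrix targets of miR-29.

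The lists of microRNA machinery, microRNA host transcripts and let-7 targets passed no set test. In the microRNA machinery list (10 tested) Dicer1 alone passed over all genes, and 1 rose and 1 fell adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.889) and fry pointing down. In the fit without DICER_KO replicate 3, 2 rose and 1 fell over all genes, and 2 and 2 adjusted over the list alone. Of 8 microRNA host transcripts 0 passed over all genes, 1 rose and 2 fell adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.292). Leaving out DICER_KO replicate 3, 0 host transcripts rose and 2 fell over all genes, and 1 and 2 adjusted over the list alone. With all libraries H19 differed by -0.78 (adjusted p = 0.112), and without DICER_KO replicate 3 it fell by 1.00 (adjusted p = 0.000125). Of 16 known let-7 targets 0 passed over all genes and 1 rose adjusted over the list alone, with a median of 0.03 (camera adjusted p = 0.571). Leaving out DICER_KO replicate 3, 3 let-7 targets rose and 2 fell by either adjustment, over all genes or adjusted over the list alone. With all libraries Hmga2, a chromatin protein gene repressed by let-7, differed by 0.68 (adjusted p = 0.108), and without DICER_KO replicate 3 it rose by 0.54 (adjusted p = 0.011).

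Genes with microRNA seed matches in their 3' UTRs were compared with genes of like 3' UTR length without them, for 15 families abundant in adipocytes or fibroblasts. Genes with an 8mer match for let-7 (430 genes) differed from the rest by -0.03 on the log2 scale, those for miR-29 (330) by -0.04, those for miR-30 (828) by 0.02 and those for miR-21 (238) by 0.07. Over the 15 families the difference ran from -0.04 to 0.07, and 0 families passed against shuffled seeds (permutation test, smallest adjusted p = 0.792), with 0 at an unadjusted p under 0.05. With the 7mer-m8 site 0 families passed and 2 had an unadjusted p under 0.05, both above the median of their shuffled seeds. These were let-7, at -0.010 against -0.037 (adjusted p = 0.286), and miR-21, at 0.066 against 0.034 (adjusted p = 0.336). On shifts of 0.1 added to fold changes shuffled among genes, the test found 13 of 15 families at an unadjusted p under 0.05, and 0 without a shift. Shuffling removes any link between fold change and 3' UTR bases, so fewer may be found in the real data. With a smallest p of 0.005 over 15 families, 1 shifted family alone could not pass the adjusted threshold. Mature microRNA levels were not measured.

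Libraries of the same group did not all resemble each other most. Across genes, Pearson's r was 0.994 between DICER_KO replicates 1 and 2, but 0.978 and 0.98 between these and replicate 3, and 0.984 to 0.987 between replicate 3 and the controls. Controls correlated at 0.99 to 0.994 with each other. On the first principal component, with 48.3% of the variance, DICER_KO replicates 1 and 2 lay at 26.4 and 22.7, replicate 3 at -11.6 and the controls from -18.8 to -7.16. On the second, with 24.8%, replicate 3 lay at -26.9 and the other libraries above 0. Genes are not independent replicates, and these values describe the libraries without a test.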

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

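Chosen only after the result was seen were the filter of at least 10 reads, the library quality weights, the seeds with as many CG pairs and the seed tests without DICER_KO replicate 3 and with each DICER_KO replicate alone; the other settings were planned. The counts of 15 genes higher and 29 lower stayed within 1.5 times under both other scalings, both other filters, both pseudocounts and limma-voom (10 to 21 higher, 24 to 35 lower). With library quality weights, which gave DICER_KO replicate 3 a weight of 0.242 and control replicate 1 a weight of 3.84, 1928 were higher and 1371 lower. Leaving out each library in turn gave 0 to 1257 higher and 1 to 726 lower, with the highest counts without DICER_KO replicate 3 and the lowest without control replicate 3; the cause was not tested for the controls. Dicer1 ran from -0.68 to -0.64 with a library left out, with adjusted p from 0.000234 to 0.147.

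With a replicate block 0 genes were higher and 2 lower, and Dicer1 differed by -0.66 (adjusted p = 0.119). Deviations of same-numbered libraries correlated at 0.20, -0.01 and -0.08. Within DICER_KO, replicate 3 correlated with replicates 1 and 2 at -0.78 and -0.73, and replicates 1 and 2 with each other at 0.14. Control replicates 2 and 3 correlated at -0.70, and control replicate 1 with each of them at -0.39. Deviations within a group of 3 sum to 0, so negative values arise by construction. Only the positive value marks replicates 1 and 2 as deviating together, away from replicate 3. Whether the numbers pair the libraries cannot be told from these values. Only control replicate 1 and DICER_KO replicate 1 correlated best with their own number.

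Of the gene list calls, 11 to 17 lists passed in every setting with a preset correlation where 12 did with all libraries, and 0 with an estimated correlation. Named genes that changed sign were all uncalled with all libraries. Acaca read 0.012 with library size only and 0.17 with quality weights, where Hmgcs1 read 0.028, Lipe 0.48 and Ucp1 0.29. The quality weights gave DICER_KO replicate 3 a low weight of 0.242. Leaving that library out also put these genes above 0, with Acaca at 0.20, Hmgcs1 at 0.14, Lipe at 0.62 and Ucp1 at 0.47. The cause of the change of Acaca with library size only was not tested. With a library left out, Acaca ran from -0.11 to 0.20, Hmgcs1 from -0.35 to 0.14, Lipe from -0.37 to 0.62, Ucp1 from -0.67 to 0.47, Pnpla2 from -0.18 to 0.61, Adipoq from -0.054 to 1.11 and Fabp4 from -0.0575 to 0.90. The medians ran from -0.088 to 0.66 in the mature adipocyte list and from -0.40 to -0.018 in the interferon list. The seed test called 0 families in all 7 settings, including each DICER_KO replicate alone, with 0 to 2 families at an unadjusted p under 0.05. A lone family could not have passed in any of them, given the smallest p of 0.005 over 15 families. The planned edgeR and DESeq2 fits were not run, although whole reads could be recovered from the values; limma-voom on those reads called 10 genes higher and 24 lower, all 34 of them among the 44.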

Other observations

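The tests of a mislabelled control library, of the adipocyte share behind the matrix genes (in all DICER_KO libraries and in replicate 3) and of the drug itself were chosen only after the result was seen.

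DICER_KO replicate 3 differed from the other DICER_KO libraries beyond the adipocyte genes. All 40 interferon and double-stranded RNA response genes lay below both other DICER_KO libraries, with a median of -0.72 against their mean, and so did all 42 oxidative phosphorylation genes (-0.64) and all 22 fatty acid oxidation genes (-0.92). The p53 targets lay higher, with a median of 0.26, above 99.97% of 10000 random lists matched on expression, which describes these libraries only. Reads on annotated microRNA genes summed to 60.4, 70.0 and 73.0 CPM in controls and 57.8, 62.1 and 61.4 CPM in DICER_KO. These poly(A) libraries did not measure mature microRNAs, so the sums do not give microRNA levels.

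The pattern of lower adipocyte transcripts in DICER_KO replicate 3 was weighed against its label, its depth and the makeup of the culture. A mislabelled control library is argued against by Dicer1, which differed from the control mean by -0.63 there, as in the other DICER_KO libraries. For the greater depth of this library, its reads were thinned to the implied size of the shallowest library (17594568). The mature adipocyte list then had a median of -1.83 against the other DICER_KO libraries, where it was -1.85 before. Thinning leaves the expected CPM of well-read genes unchanged, so it could not test other differences that go with depth. For fewer or less mature adipocytes in this culture, the 21 preadipocyte and fibroblast markers had a median of -0.13 (95% bootstrap interval over genes -0.34 to 0.11). It lay at the 5.69th percentile of random lists. Of the 21 markers 14 lay below the mean of the other DICER_KO libraries, while the preadipocyte marker Dlk1 lay 0.86 above it. The markers include Col1a1, Col1a2 and Col3a1 of the matrix list, whose median lay at -0.22 in the same comparison. Lower matrix genes would thus lower the markers' median whatever the cell share. A median below 0 and below the middle of the random lists had been set beforehand as speaking against this explanation, and was met. The interval was not part of that prediction and includes 0, so the explanation may remain a candidate. The design names no difference between these libraries.

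The lower matrix genes held in DICER_KO replicate 3, where all 13 tested matrix targets of miR-29 lay below the control mean, with a median of -0.56. The fall runs against the direction that loss of microRNA repression predicts for targets. In that library all 20 tested members of the mature adipocyte list lay below the control mean, with a median of -1.03 (95% bootstrap interval -1.22 to -0.97). This argues against a larger share of adipocytes there only if transcripts per adipocyte did not fall, which was not measured. The low list was known before this test was chosen, so the interval adds no separate support. In DICER_KO replicates 1 and 2 that list lay higher, at 0.64 and 0.70, and a larger share could still lower matrix transcripts there. Over the 3 libraries the 18 preadipocyte and fibroblast markers outside the matrix list had a median of -0.24, against -0.37 for the matrix list. The difference of 0.13 had an interval of -0.052 to 0.39 that includes 0. Those 18 markers still include matrix genes such as Fn1, so they cannot separate a fall of matrix genes from a change in cell share. Both intervals resample genes, not cultures. Exposure to 4-hydroxytamoxifen itself cannot be told apart from the deletion, since 0 libraries had the drug and an intact Dicer1 gene.

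For the 44 genes past the threshold, the 6 libraries form 10 splits into groups of 3, too few for a share under 0.05. Only 1 split, the real one, gave as many as 44 genes, and the highest of the others gave 0.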
